A study of Arabidopsis thaliana with 42 samples.

How the data were processed

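The deposited table held raw whole-number counts of reads per gene for 42 RNA-seq libraries of whole 5-day-old Arabidopsis thaliana seedlings, with no normalisation by the authors apparent in the values. Per the labels' protocols, 12 libraries were made from poly(A)+ RNA, of which 6 were from total RNA and 6 from the polysome-bound population, and 30 were made from rRNA-depleted RNA of seedlings given cordycepin. Per the submitters' processing notes, Bowtie2 2.2.5 and TopHat2 2.0.14 were used with the TAIR10 genome. The counting program, its strand setting and the annotation version are not given in the sources used here, so reads of near-identical copies, overlapping genes and antisense pairs may be split or merged in these counts. How polysomes were isolated is also not given in the sources used here.

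Of the 27667 loci in the table, 27455 were matched to the names table of the TAIR10.1 assembly, which was used for gene names only. No coordinates are given because TAIR10.1 is not the build named by the submitters. For 212 loci the table held no value in the poly(A)+ libraries (88 chloroplast genes, 122 mitochondrial genes and 2 nuclear loci), so these were tested in the rRNA-depleted set only. No column of the table was left out.

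Samples were grouped by genotype, RNA population and time as the labels state, giving 14 groups of 3 replicates. The labels do not say that replicates were separate cultures, so p-values measure the spread between these samples, which may be technical. No replicate pair was a duplicate within counting noise, since the chi-square per degree of freedom between replicates ran from 3.02 to 22.9. Totals per library ran from 4611462 to 30654342 counts in the poly(A)+ set and from 11463206 to 22251739 in the rRNA-depleted set. Intervals and detection floors cover counting error only.

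Tests were run in R 4.3.3 with edgeR 4.0.16. Libraries were scaled by TMM factors, genes were kept by filterByExpr (minimum count 10, minimum total 15), and the robust quasi-likelihood test was used, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The 12 poly(A)+ libraries were fitted together with 1 mean per group. From that fit came the genotype contrast in total RNA, the genotype contrast in polysome RNA, the polysome to total contrast within each genotype, and the interaction of genotype and RNA population, here called ribosome association. The 30 rRNA-depleted libraries were fitted in 2 ways, with a mean for each of the 10 groups for the contrast at 0 min, and with a straight line of log2 abundance against time for each genotype. Slopes are in log2 units per hour. Each standard error (SE) was back-calculated as the absolute log2 value over the square root of the F statistic of its test, and is approximate. TMM sets the slope of a typical transcript near 0, so a slope is relative to the bulk of transcripts and is not an absolute half-life.

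The designs, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined, except where a choice is said to be later. The rule for named genes took the 3 target helicases, the 8 largest changes in each direction among genes past the threshold with a mean log2 CPM of at least 3 and no overlap between the replicates of the groups compared (by chance 10% of genes do not overlap in 3 against 3), and up to 4 members of each list with the smallest p. Not every gene that the rule allows is named. The 18 lists held the target helicases, mRNA decay factors, salicylic acid immunity, pattern-triggered defence, rapid stress regulators, jasmonate, ethylene, heat shock, abscisic acid and dehydration, hypoxia, nuclear photosystem and rubisco genes, cytosolic ribosomal proteins, Aux/IAA and SAUR genes, cell expansion, cell cycle, circadian clock, root markers and seed maturation markers. Of 346 list members 345 were kept, and PAT1 was left out because the names table gives that symbol to another locus. Lists other than the targets were tested with camera of limma 3.58.1 at the preset correlation of 0.01, with camera at an estimated correlation, and with fry, adjusted by Benjamini-Hochberg over the 17 lists of a comparison. Camera asks whether a list changed more than other genes, and fry whether its members changed at all. Fry values are given for a few lists only.

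A gene with 0 counts in every library of a group is given a lower bound of its fold change against a floor of 3 counts over the group, and a gene with 1 to 3 counts a fold with an exact 95% counting interval. The relation between slopes and abundance used 2 fits that share no library. The classes of genes by Col-0 slope were made from 1 Col-0 series and the slope difference from the other 2 replicates of each genotype.

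The tests were tried on simulated counts with 200 changed genes. The changes went in both directions alike, all other genes were flat, and libraries were drawn independently. In the real total RNA 64.6% of genes were called, so the simulated rates need not hold for these data. For total RNA (20949 genes) 40.3%, 91.0% and 97.0% of changes of log2 0.5, 1 and 2 were recovered and 19 unchanged genes were called. For ribosome association the shares were 8.96%, 62.7% and 92.4% with 12 unchanged genes called, and for 0 min (21486 genes) 16.4%, 68.7% and 92.4% with 7. For the slope difference, 2.99%, 44.8% and 80.3% of changes of 0.25, 0.5 and 1 per hour were recovered, with 3 unchanged genes called. Without a simulated difference the slope classes gave medians of -0.005 in the fastest-lost class and 0.002 in the class with the highest slopes.

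Alternatives were DESeq2 1.42.0 size factors in the same fit, library size alone, the DESeq2 Wald test, no count filter, a filter of 1 CPM in 3 libraries, organelle genes removed, the replicate number as a block, fits of the compared groups alone, each library or time series left out in turn, slopes from 0 to 60 min or from 15 to 120 min, library factors set by the photosystem list, and time as a factor.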

Results

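RNA was sequenced from whole 5-day-old seedlings of Arabidopsis thaliana accession Col-0, the wild type, and of a line labelled rh6812. The label names the DEAD-box RNA helicases RH6, RH8 and RH12, relatives of yeast DHH1 and animal DDX6, which act in mRNA decapping and translational repression. The 42 libraries formed 14 groups of 3 replicates. Total poly(A)+ RNA was counted in 6 libraries (11783437 to 25864031 counts each) and polysome-bound poly(A)+ RNA in 6 (4611462 to 30654342). The other 30 libraries (11463206 to 22251739 counts) were rRNA-depleted RNA of seedlings treated with cordycepin, an adenosine analogue that stops RNA synthesis, and taken at 0, 15, 30, 60 and 120 min. The biological coefficient of variation within a group was lowest in Col-0 polysome RNA, at 7.72%, and 9.07% to 9.49% in the other poly(A)+ groups. In the rRNA-depleted groups it was 11.3% to 15.4%, and higher still in Col-0 at 0 min.

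The helicase transcripts did not all follow the label. RH8 (AT4G00660) fell from 32.7 ± 0.165 CPM in Col-0 to 2.84 ± 0.732 CPM in total RNA of the libraries labelled rh6812 (SD, n = 3, log2 change -3.48 ± 0.14 SE). It fell from 29.7 ± 1.89 to 3.12 ± 1.09 CPM in polysome RNA and from 34.7 ± 0.913 to 3.42 ± 0.344 CPM in rRNA-depleted RNA at 0 min. RH12 (AT3G61240) fell from 38.5 ± 1.96 to 24.4 ± 1.52 CPM in total RNA (-0.66 ± 0.10). It also fell from 42.4 ± 2.14 to 22.1 ± 3.24 CPM in polysome RNA, and by 0.87 ± 0.11 to 9.65 ± 0.597 CPM at 0 min. RH6 (AT2G45810) went against the label. It rose from 54.5 ± 1.96 to 132 ± 4.97 CPM in total RNA (1.27 ± 0.08, edgeR adjusted p = 9.9e-15), from 68.1 ± 2.59 to 97.1 ± 3.69 CPM in polysome RNA (0.51 ± 0.08) and from 35.3 ± 1.89 to 378 ± 41.3 CPM at 0 min (3.42 ± 0.14, adjusted p = 4.9e-16). In total RNA the RH6 values were 56.0, 55.2 and 52.3 CPM in Col-0 and 136, 134 and 126 CPM in the libraries labelled rh6812. The ratio of polysome to total RH6 was lower in the libraries labelled rh6812 (-0.76 ± 0.11, adjusted p = 2.2e-05), and after cordycepin RH6 was lost faster there, at -0.77 ± 0.06 per hour against -0.26 ± 0.07 in Col-0 (difference -0.51 ± 0.09, adjusted p = 0.00018). That slope difference was no longer past the threshold with times up to 60 min only. Every direction given for the mutant line rests on labels that RH8 and RH12 go with and RH6 goes against.

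**Figure D1:**
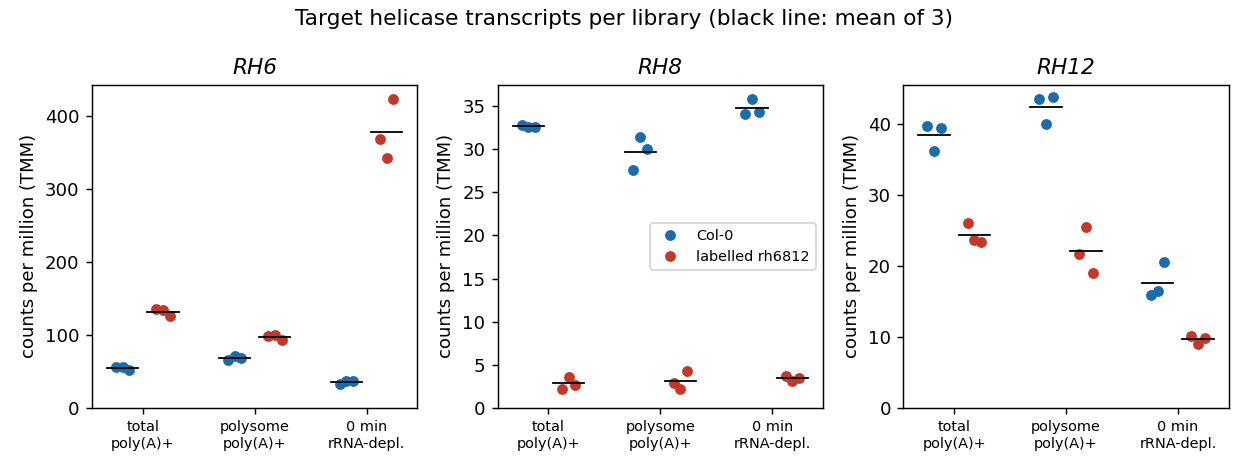
Abundance in CPM of RH6, RH8 and RH12 (vertical axes, TMM-scaled) in each library of total poly(A)+ RNA, polysome poly(A)+ RNA and rRNA-depleted RNA at 0 min, with points for libraries and black lines for the means of 3. RH8 and RH12 lie lower in the libraries labelled rh6812, and RH6 lies higher, at a mean of 378 against 35.3 CPM at 0 min.

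Total poly(A)+ RNA was compared to ask which transcripts differed in steady-state abundance. Most members of the salicylic acid, jasmonate, heat shock and ribosomal protein lists rose in the libraries labelled rh6812, and most members of the auxin-response and photosystem lists fell. Camera called these lists at its preset correlation, and none of them at an estimated one (adjusted p = 0.16 to adjusted p = 0.54 with an estimated correlation). Fry, which keeps the correlation between genes but does not compare a list with other genes, called all of them (fry adjusted p = 3.6e-07 to adjusted p = 0.0013). Among the largest increases were PCR1 (AT1G14880, 11.09 ± 0.60, from 0.155 ± 0.140 to 277 ± 77.1 CPM, adjusted p = 2e-07), the defence-associated PCC1 (AT3G22231, 10.62 ± 0.65, from 0.232 ± 0.210 to 295 ± 102 CPM, adjusted p = 5.7e-07), LURP1 (AT2G14560, 9.04 ± 0.47, from 0.393 ± 0.0743 to 208 ± 62.5 CPM) and the pathogenesis-related PR1 (AT2G14610, 9.32 ± 0.90, from 0.0786 ± 0.0792 to 42.4 ± 16.3 CPM, adjusted p = 1.5e-05), with CPM ± SD over n = 3 libraries and log2 changes ± SE. AT3G28510 had 0 counts in the Col-0 libraries and was at least 513-fold higher, against a floor of 3 counts over the group. Among the largest decreases were AT5G44260 (-5.06 ± 0.16, from 37.1 ± 4.37 to 1.11 ± 0.0446 CPM, adjusted p = 8.5e-22), the blue-light receptor FKF1 (AT1G68050, -4.57 ± 0.31, from 27.2 ± 6.48 to 1.18 ± 0.488 CPM), THA1 (AT1G08630, -4.88 ± 0.39) and AT5G02540 (-4.40 ± 0.16). Of 20949 genes tested, 13536 passed the threshold, 6753 higher and 6783 lower, of which 2915 and 1895 by more than 2-fold. The median change of all genes was -0.03 with TMM and -0.18 with library size alone, with which the split was 5482 higher and 8448 lower. With DESeq2 size factors the split was 6893 higher and 6643 lower.

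Counts adjusted over a list alone are given only where they differ from those over all genes. Of 24 tested genes of salicylic acid immunity, 20 rose and 0 fell (median 2.08), among them the nucleotide hydrolase NUDT7 (AT4G12720, 1.57 ± 0.10, adjusted p = 8.8e-15), the transcription factor SARD1 (AT1G73805, 2.16 ± 0.14) and the glucanase PR2 (AT3G57260, 7.85 ± 0.32, adjusted p = 5.3e-11). The list was called by camera (adjusted p = 4e-10) but not with its own correlation (adjusted p = 0.16 with an estimated correlation). Of 24 jasmonate genes 22 rose and 1 fell (camera adjusted p = 1.5e-05, and adjusted p = 0.18 with an estimated correlation). Among them were the lipoxygenase LOX4 (AT1G72520, 4.48 ± 0.19, from 1.03 ± 0.484 to 20.8 ± 2.34 CPM, adjusted p = 1.4e-18), the cyclase AOC1 (AT3G25760, 2.00 ± 0.16), VSP2 (AT5G24770, 2.56 ± 0.20) and the repressor JAZ9 (AT1G70700, 1.57 ± 0.12). Of 16 heat shock genes 14 rose and 1 fell (14 and 2 adjusted over the list alone, camera adjusted p = 2.5e-10, and adjusted p = 0.16 with an estimated correlation). Examples were the chaperones HSP90.1 (AT5G52640, 4.66 ± 0.11, from 11.1 ± 1.38 to 276 ± 39.7 CPM, adjusted p = 3.1e-24) and HSP17.6A (AT5G12030, 6.70 ± 0.34) and the factor HSFB1 (AT4G36990, 1.51 ± 0.10). Of 26 rapid stress regulators 18 rose and 4 fell (camera adjusted p = 0.0044, and adjusted p = 0.29 with an estimated correlation). They included CML37 (AT5G42380, 6.40 ± 0.32) and the zinc finger factor ZAT10 (AT1G27730, 2.27 ± 0.18). Of 28 genes of pattern-triggered defence 14 rose and 7 fell (camera adjusted p = 0.21). The kinase MPK11 (AT1G01560, 3.70 ± 0.34) and the NADPH oxidase RBOHD (AT5G47910, 2.04 ± 0.16) were higher and WRKY22 (AT4G01250, -1.95 ± 0.13) lower. Of 22 abscisic acid and dehydration genes 12 rose and 3 fell (camera adjusted p = 0.0016, and adjusted p = 0.16 with an estimated correlation). Among them were KIN1 (AT5G15960, 3.73 ± 0.12, from 3.92 ± 0.478 to 51.4 ± 5.76 CPM, adjusted p = 4.7e-21) and RD22 (AT5G25610, 2.22 ± 0.11). Of 11 hypoxia genes 8 rose and 1 fell (camera adjusted p = 0.028, and adjusted p = 0.19 with an estimated correlation). Examples were the alcohol dehydrogenase ADH1 (AT1G77120, 2.64 ± 0.18) and the haemoglobin HB1 (AT2G16060, 1.38 ± 0.13). Of 12 ethylene genes 2 rose and 8 fell (camera adjusted p = 0.028, and adjusted p = 0.18 with an estimated correlation). They included ACS8 (AT4G37770, -4.31 ± 0.37), EBF2 (AT5G25350, -1.19 ± 0.11) and CTR1 (AT5G03730, -0.94 ± 0.09) lower.

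All 24 cytosolic ribosomal protein genes tested rose (camera adjusted p = 6.1e-10, and adjusted p = 0.16 with an estimated correlation). Members were RPL10C (AT1G66580, 1.42 ± 0.09) and RPS6A (AT4G31700, 1.36 ± 0.09, from 343 ± 35.1 to 881 ± 61.7 CPM, adjusted p = 3.5e-14). Of 42 nuclear photosystem and rubisco genes 6 rose and 28 fell (camera adjusted p = 1.5e-05, and adjusted p = 0.54 with an estimated correlation). The antenna genes LHCA2 (AT3G61470, -1.50 ± 0.10, from 3890.0 ± 513 to 1378 ± 109 CPM, adjusted p = 6.7e-14) and LHCA4 (AT3G47470, -1.42 ± 0.10) were among the decreases. LHCB1.4 (AT2G34430, -2.05 ± 0.12) also fell, but the LHCB1 copies are near-identical and their counts are uncertain. Of 21 early auxin-response genes 1 rose and 19 fell (camera adjusted p = 1.3e-07, and adjusted p = 0.16 with an estimated correlation). Examples were IAA29 (AT4G32280, -5.56 ± 0.31, from 10.5 ± 3.01 to 0.222 ± 0.00410 CPM), IAA19 (AT3G15540, -1.66 ± 0.14) and IAA2 (AT3G23030, -1.29 ± 0.11). Of 17 clock genes 4 rose and 12 fell (camera adjusted p = 0.1). The morning gene LHY (AT1G01060, 3.63 ± 0.12, from 3.84 ± 0.339 to 46.9 ± 3.08 CPM, adjusted p = 6.6e-21) rose and the later PRR5 (AT5G24470, -3.19 ± 0.13, from 41.2 ± 5.17 to 4.54 ± 0.543 CPM, adjusted p = 6.4e-19) and GI (AT1G22770, -1.92 ± 0.10) fell, in the same libraries as the changes of the stress, auxin and photosystem lists. Of 15 cell expansion genes 4 rose and 7 fell (camera adjusted p = 0.96), with the expansins EXPA1 (AT1G69530, 1.73 ± 0.09) higher and EXPA11 (AT1G20190, -2.23 ± 0.13) lower, and the list's median of 0.01 and mean of -0.18 differ in sign. Of 20 mRNA decay factors 3 rose and 8 fell (camera adjusted p = 0.53, fry adjusted p = 0.027). The deadenylase CAF1B (AT5G22250, 1.26 ± 0.14) was higher and the decapping enzyme DCP2 (AT5G13570, -0.57 ± 0.11), SKI2 (AT3G46960, -0.87 ± 0.13) and RRP44A (AT2G17510, -0.72 ± 0.13) were lower. Of 8 cell cycle genes 4 rose and 0 fell (camera adjusted p = 0.36). An example was CDKB2;1 (AT1G76540, 0.78 ± 0.13). When Col-0 total replicate 1 was left out, or with library size alone, 2 rose. Of 13 root markers 6 rose and 2 fell (camera adjusted p = 0.36). The nitrate transporter NRT2.1 (AT1G08090, 2.08 ± 0.23) and PRP3 (AT3G62680, 1.44 ± 0.19) were higher. None of the 5 tested seed maturation markers passed with edgeR, over all genes or adjusted over the list alone, or with the DESeq2 Wald test, and their median of 0.54 and the downward camera direction (adjusted p = 0.95) differ in sign.

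**Figure D2:**
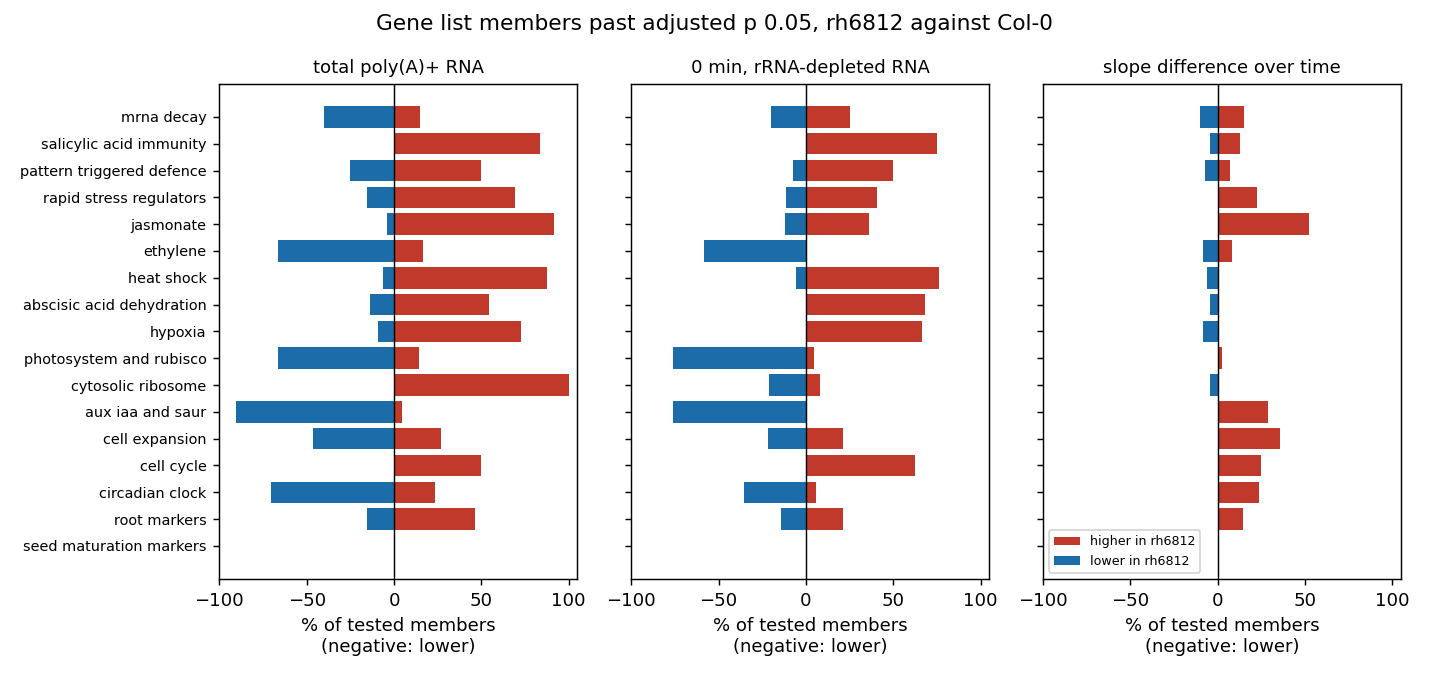
Share of the tested members of each gene list that passed an adjusted p of 0.05 (horizontal axis in percent, lower plotted as negative) for total poly(A)+ RNA, for rRNA-depleted RNA at 0 min and for the slope difference after cordycepin, red for higher and blue for lower in the libraries labelled rh6812. In total RNA 22 of 24 jasmonate genes were higher, at 0 min 32 of 42 photosystem genes were lower, and 13 of 25 jasmonate genes had a higher slope; the ribosomal protein list at 0 min turned from 2 higher and 5 lower to 9 higher and 1 lower with library size alone.

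Polysome-bound poly(A)+ RNA was compared to ask which transcripts differed in the ribosome-bound population. The pathogenesis-related PR1 (10.79 ± 0.81, from 0.105 ± 0.0696 to 172 ± 75.8 CPM, adjusted p = 2.5e-06), PCR1 (11.31 ± 0.57) and LURP1 (9.75 ± 0.48) were again among the largest increases in the libraries labelled rh6812. ARD3 (AT2G26400) had 0 counts in Col-0 polysome RNA and was at least 588-fold higher, and CYP82C2 (AT4G31970) likewise at least 519-fold higher, against a floor of 3 counts over the group. The largest decreases included AT5G22500 (-6.13 ± 0.18, from 63.4 ± 4.76 to 0.781 ± 0.270 CPM, adjusted p = 9.1e-23), PAR1 (AT2G42870, -5.94 ± 0.28), AT5G02540 (-5.84 ± 0.20) and FKF1 (-5.72 ± 0.42). In this population 13298 genes passed, 6325 higher and 6973 lower, and the median change of all genes was -0.05 with TMM and -0.14 with library size alone. With DESeq2 size factors the split was 6656 higher and 6517 lower. Across 20949 genes the changes in total and polysome RNA, which share no library, had r = 0.877, a description across genes that are not independent replicates. Of 10973 genes called in both, 10841 (98.8%) had the same direction.

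Of 24 salicylic acid genes in polysome RNA 21 rose and 0 fell (camera adjusted p = 1.8e-12, and adjusted p = 0.16 with an estimated correlation). Examples were SARD1 (2.78 ± 0.14) and the lipase-like PAD4 (AT3G52430, 2.22 ± 0.14). Of 24 jasmonate genes 21 rose and 1 fell (camera adjusted p = 2.6e-06, and adjusted p = 0.17 with an estimated correlation). They included LOX4 (4.42 ± 0.21) and AOC3 (AT3G25780, 3.63 ± 0.21). Of 16 heat shock genes 14 rose and 2 fell (camera adjusted p = 1.4e-08, and adjusted p = 0.16 with an estimated correlation). A member was HSP90.1 (4.27 ± 0.12, from 6.57 ± 0.587 to 125 ± 4.96 CPM). The list of abscisic acid and dehydration had 12 higher and 5 lower of 22 (13 and 5 adjusted over the list alone, camera adjusted p = 0.0023, and adjusted p = 0.17 with an estimated correlation). A dehydration gene that rose was KIN1 (5.09 ± 0.14, from 2.42 ± 0.150 to 84.1 ± 10.4 CPM, adjusted p = 2.4e-23). Rapid stress regulators had 17 higher and 5 lower of 26 (camera adjusted p = 0.0038, and adjusted p = 0.26 with an estimated correlation), and pattern-triggered defence 16 higher, WRKY33 (AT2G38470, 1.51 ± 0.13) among them, and 8 lower of 28 (camera adjusted p = 0.083). Of 11 hypoxia genes 6 rose and 1 fell (camera adjusted p = 0.083), and of 12 ethylene genes 2 rose and 8 fell (camera adjusted p = 0.041, and adjusted p = 0.21 with an estimated correlation). All 24 ribosomal protein genes rose (camera adjusted p = 4.3e-07, and adjusted p = 0.18 with an estimated correlation). An example was RPL10C (1.33 ± 0.09). Of 42 photosystem genes 7 rose and 31 fell (camera adjusted p = 1.7e-05, and adjusted p = 0.5 with an estimated correlation). A member was LHCA2 (-1.63 ± 0.10). Of 21 auxin-response genes 0 rose and 19 fell (0 and 20 adjusted over the list alone, camera adjusted p = 2.9e-10, and adjusted p = 0.17 with an estimated correlation). Members were IAA19 (-2.48 ± 0.16) and IAA14 (AT4G14550, -1.97 ± 0.13).

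Of 15 cell expansion genes in polysome RNA 4 rose and 8 fell (4 and 9 adjusted over the list alone, camera adjusted p = 0.47). An expansin that fell was EXPA11 (-3.19 ± 0.15). Of 8 cell cycle genes 7 rose and 0 fell (camera adjusted p = 0.075), with CDKB2;1 (1.34 ± 0.14). The clock list had 4 higher, LHY (4.63 ± 0.14) among them, and 13 lower (camera adjusted p = 0.16). Of 20 mRNA decay factors 5 rose and 9 fell (camera adjusted p = 0.76). Of 13 root markers 3 rose and 2 fell (camera adjusted p = 0.97), but 1 rose and 2 fell without Col-0 polysome replicate 1 and 1 rose and 1 fell without rh6812 polysome replicate 1. None of the 5 seed markers passed with edgeR or with the DESeq2 Wald test, but 2 of 12 rose without a count filter and 1 of 5 with a replicate block, and leaving out single polysome libraries gave at most 2 higher (without rh6812 replicate 2) and 1 lower (without rh6812 replicate 3). The list's median of -0.22 and mean of 0.69 differ in sign.

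Ribosome association, the change of the polysome to total ratio between genotypes, was tested as an interaction. The glycine-rich protein gene GRP9 (AT2G05440, 2.14 ± 0.12, adjusted p = 1.4e-13), the copper transporter COPT2 (AT3G46900, 2.25 ± 0.22, adjusted p = 5.4e-08), the thioredoxin TRX5 (AT1G45145, 2.06 ± 0.16) and the nitrate transporter NRT1.5 (AT1G32450, 2.07 ± 0.18) gained polysome share relative to total RNA in the libraries labelled rh6812 (log2 change of the ratio ± SE, n = 3 per group). The epidermal gene PDF1 (AT2G42840, -3.37 ± 0.19, adjusted p = 4e-12), AT5G22500 (-3.60 ± 0.24, adjusted p = 4e-12), MLP-300B (AT3G16440, -3.64 ± 0.25) and AT1G06080 (-3.65 ± 0.26) lost it. Of 20949 genes, 2044 passed, 692 higher and 1352 lower, of which 301 and 542 by more than 2-fold. Without rh6812 polysome replicate 1 the counts were 745 higher and 739 lower, and with library size alone 794 and 1004. At an unadjusted p under 0.05 there were 4758 genes. Within Col-0, 12083 genes differed between polysome and total RNA (6425 higher in polysomes, 5658 lower), and within the libraries labelled rh6812 11140 (5444 and 5696). With library size alone these splits were 3840 and 8037, and 3541 and 7363, and the medians of all genes were -0.19 and -0.18, against 0.04 and -0.01 with TMM.

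Auxin-response genes had the most calls of lost polysome share among the lists, and root markers had the lowest median (-0.80). Of 21 tested 0 rose and 6 fell (1 and 10 adjusted over the list alone, median -0.73, camera adjusted p = 0.00066, and adjusted p = 0.65 with an estimated correlation). Examples were IAA17 (AT1G04250, -0.90 ± 0.14, adjusted p = 4.7e-05), IAA14 (-1.02 ± 0.18) and IAA7 (AT3G23050, -0.61 ± 0.12). Of 15 cell expansion genes 0 rose and 3 fell (0 and 5 adjusted over the list alone, camera adjusted p = 0.029, and adjusted p = 0.65 with an estimated correlation). They included EXPA11 (-0.96 ± 0.19) and EXPA10 (AT1G26770, -0.71 ± 0.15). When Col-0 total replicate 3 or rh6812 total replicate 2 was left out 5 fell. Of 24 salicylic acid genes 2 rose and 0 fell (3 and 0 adjusted over the list alone, camera adjusted p = 0.0076, and adjusted p = 0.91 with an estimated correlation). An example was PAD4 (1.06 ± 0.18, adjusted p = 2e-04). When Col-0 polysome replicate 1, Col-0 total replicate 1 or rh6812 total replicate 3 was left out 1 rose. Of 24 jasmonate genes 3 rose and 0 fell (camera adjusted p = 0.12). A member was AOC3 (2.04 ± 0.28, adjusted p = 8.2e-06). Of 22 abscisic acid genes 5 rose and 3 fell (5 and 5 adjusted over the list alone), with KIN1 (1.36 ± 0.20), the phosphatase HAI1 (AT5G59220, 2.00 ± 0.39) and the factor ABF3 (AT4G34000, 0.64 ± 0.14) higher, and the list's median of -0.18 and mean of 0.06 differ in sign. Of 42 photosystem genes 4 rose and 0 fell (5 and 1 adjusted over the list alone), all 4 being near-identical LHCB1 copies whose counts are uncertain, and the median of -0.14 and the upward camera direction differ in sign. The cell cycle list was called by camera (median 0.54, camera adjusted p = 0.02, and adjusted p = 0.65 with an estimated correlation) with 1 member past the threshold over all genes and 4 adjusted over the list alone, and 0 passed over all genes without any of the 3 Col-0 polysome libraries in turn, among others. In the clock list LHY (1.00 ± 0.20) gained polysome share and ELF4 (AT2G40080, -1.50 ± 0.32) lost it. Of 13 root markers 0 rose and 2 fell (1 and 2 adjusted over the list alone, camera adjusted p = 0.3). No other list had more than 2 members past the threshold in either direction.

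At 0 min the rRNA-depleted libraries gave a comparison of abundance from other samples and another library type. Most members of the salicylic acid, heat shock, abscisic acid and hypoxia lists rose in the libraries labelled rh6812, and most members of the photosystem and auxin-response lists fell. Of these lists hypoxia also passed with an estimated correlation (adjusted p = 0.012), and the others did not (adjusted p = 0.17 to adjusted p = 0.35 with an estimated correlation). Fry called each of these lists (fry adjusted p = 1.7e-10 to adjusted p = 0.00021). PCC1 (9.04 ± 1.04), AT5G42530 (7.52 ± 0.45, adjusted p = 1.8e-11), PBS3 (AT5G13320, 7.31 ± 0.81), an enzyme of salicylic acid synthesis, and the iron-response factor bHLH38 (AT3G56970, 6.33 ± 0.49) had some of the largest increases, and PCR1, with 3 counts in Col-0, was 395-fold higher (95% counting interval 135 to 1919). The gibberellin-responsive GASA6 (AT1G74670, -3.42 ± 0.38, from 47.4 ± 9.17 to 4.34 ± 1.37 CPM, adjusted p = 2.3e-07), the auxin-conjugating enzyme GH3.3 (AT2G23170, -3.04 ± 0.39, from 67.5 ± 22.4 to 8.22 ± 2.79 CPM, adjusted p = 1.9e-06), NRT1.5 (-2.57 ± 0.24) and AT5G02540 (-3.85 ± 0.78) had some of the largest decreases. Of 21486 genes tested 10390 passed, 5240 higher and 5150 lower, of which 2184 and 1271 by more than 2-fold. The median change of all genes was -0.02 with TMM and 0.20 with library size alone, with which the split was 7203 higher and 2573 lower. The chloroplast share of counts at 0 min was 53.0 ± 2.16% in Col-0 and 44.7 ± 1.69% in the libraries labelled rh6812 (SD, n = 3, exact permutation p = 0.1, two-sided, the smallest that 3 against 3 allows), and moved with genotype beside every list described here. Across 20319 genes the changes at 0 min and in total poly(A)+ RNA had r = 0.708 and rho = 0.595, and 6473 of 7368 genes called in both (87.9%) had the same direction. Independent lists of these sizes would share 1629 genes higher and 1627 lower, against 3349 and 3124 seen.

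At 0 min 18 rose and 0 fell of 24 salicylic acid genes (19 and 0 adjusted over the list alone, camera adjusted p = 2.2e-07, and adjusted p = 0.26 with an estimated correlation). Examples were PR5 (AT1G75040, 4.31 ± 0.32, adjusted p = 1.2e-10) and SARD1 (2.64 ± 0.21). Of 28 genes of pattern-triggered defence 14 rose and 2 fell (17 and 2 adjusted over the list alone, camera adjusted p = 0.0013, and adjusted p = 0.42 with an estimated correlation). They included the kinase FRK1 (AT2G19190, 2.27 ± 0.24) and PAD3 (AT3G26830, 3.06 ± 0.47) of camalexin synthesis. Of 17 heat shock genes 13 rose and 1 fell (camera adjusted p = 2.3e-05, and adjusted p = 0.17 with an estimated correlation). Members were HSP70 (AT3G12580, 3.27 ± 0.43, from 15.0 ± 6.06 to 145 ± 38.2 CPM) and MBF1C (AT3G24500, 1.47 ± 0.18). Of 22 abscisic acid genes 15 rose and 0 fell (camera adjusted p = 0.00015, and adjusted p = 0.35 with an estimated correlation). Among them were RD20 (AT2G33380, 3.63 ± 0.43) and HAI1 (3.20 ± 0.54). Of 12 hypoxia genes 8 rose and 0 fell (camera adjusted p = 2.9e-05), with the decarboxylase PDC1 (AT4G33070, 2.53 ± 0.19, adjusted p = 5.8e-11) and HB1 (3.21 ± 0.38), and this list also passed with an estimated correlation (adjusted p = 0.012). Of 25 jasmonate genes 9 rose and 3 fell (camera adjusted p = 0.16). VSP2 (3.15 ± 0.40) was higher and JAZ3 (AT3G17860, -1.04 ± 0.14) lower. Of 27 rapid stress regulators 11 rose and 3 fell (camera adjusted p = 0.14). A member was ZAT12 (AT5G59820, 1.97 ± 0.26). Of 12 ethylene genes 0 rose and 7 fell (camera adjusted p = 0.15). An example was CTR1 (-0.67 ± 0.12). When rh6812 replicate 1 was left out 4 fell, and with library size alone 1 rose and 2 fell.

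Of 42 photosystem genes at 0 min 2 rose and 32 fell (camera adjusted p = 1.1e-10, and adjusted p = 0.35 with an estimated correlation). An example was LHCA2 (-1.67 ± 0.14, from 1278 ± 167 to 401 ± 29.0 CPM, adjusted p = 3.6e-10). Of 21 auxin-response genes 0 rose and 16 fell (0 and 19 adjusted over the list alone, camera adjusted p = 9.5e-05, and adjusted p = 0.28 with an estimated correlation). Examples were IAA29 (-3.83 ± 0.43) and IAA3 (AT1G04240, -1.34 ± 0.16). Of 24 ribosomal protein genes 2 rose and 5 fell (camera adjusted p = 0.97), but 9 rose and 1 fell with library size alone. RPL10C (0.92 ± 0.11) and RPS6A (0.75 ± 0.10) were higher. Of 17 clock genes 1 rose and 6 fell (camera adjusted p = 0.007), with LNK2 (AT3G54500, -2.24 ± 0.13, adjusted p = 7.6e-13), PRR7 (AT5G02810, -1.83 ± 0.15) and LHY (-0.97 ± 0.19, from 73.8 ± 9.62 to 37.6 ± 2.83 CPM, adjusted p = 0.00018) lower, and this list also passed with an estimated correlation (adjusted p = 0.042). LHY and CCA1 were lower at 0 min and higher in total poly(A)+ RNA. Of 20 mRNA decay factors 5 rose and 4 fell (camera adjusted p = 0.55). UPF1 (AT5G47010, -0.87 ± 0.11) and RRP44A (-1.05 ± 0.12) were lower. Without replicate 1 or 2 of either genotype 2 rose and 4 fell. Of 8 cell cycle genes 5 rose and 0 fell (camera adjusted p = 0.084). A member was CDKB2;1 (1.04 ± 0.16). When Col-0 replicate 1 or 3 or rh6812 replicate 2 or 3 was left out 3 rose. Of 14 cell expansion genes 3 rose and 3 fell (camera adjusted p = 0.86). EXPA10 (1.92 ± 0.35) was higher and EXPA6 (AT2G28950, -1.24 ± 0.16) lower. Of 14 root markers 3 rose and 2 fell (camera adjusted p = 0.92). NRT2.1 (1.51 ± 0.40) was higher. None of the 11 tested seed markers passed with edgeR, over all genes or adjusted over the list alone, or with the DESeq2 Wald test, with a median of 0.83.

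The cordycepin series asked how fast each transcript was lost relative to the bulk. In Col-0 the largest losses among transcripts above the abundance bound for named genes were those of MAKR6 (AT5G52900, -2.60 ± 0.30), BBX14 (AT1G68520, -1.93 ± 0.22), BT2 (AT3G48360, -1.82 ± 0.23), AT5G38700 (-1.82 ± 0.30), the chloroplast regulator GLK2 (AT5G44190, -1.78 ± 0.13), BT4 (AT5G67480, -1.71 ± 0.16), MYB34 (AT5G60890, -1.71 ± 0.19) and BT1 (AT5G63160, -1.70 ± 0.20) (slope in log2 per hour ± SE, 15 libraries of 3 series, fitted as independent). Of 21486 genes 10894 had a Col-0 slope past the threshold, 5864 negative and 5030 positive relative to the bulk. A positive slope can be slower loss than the bulk or a rise after cordycepin. In Col-0 FRK1 went from 2.42 CPM at 0 min to 8.54 CPM at 120 min. Of the called Col-0 slopes 272 were above 1 log2 unit per hour. In the libraries labelled rh6812 4662 slopes passed, 2491 negative and 2171 positive, and 2616 and 2598 without series 1 or series 2. With DESeq2 size factors the larger direction turned, to 5859 positive and 5246 negative in Col-0 and 2521 and 2335 in the libraries labelled rh6812. With library size alone the splits were 1373 positive and 9977 negative in Col-0 and 506 and 4169 in the libraries labelled rh6812, and with factors from the photosystem list 1282 and 8402, and 348 and 3041. The median of all Col-0 slopes was -0.01 with TMM and 0.02 with DESeq2 size factors. It was -0.19 with library size alone and -0.17 with photosystem factors, so the sign of a slope is relative to the TMM reference. Times up to 60 min alone gave 6483 Col-0 genes and 1128 in the libraries labelled rh6812, for which times from 15 min gave 2684. The chloroplast share of counts, as the mean over 5 times of each series, was 55.6 ± 1.08% in Col-0 and 45.8 ± 0.517% in the libraries labelled rh6812 (SD, n = 3, exact permutation p = 0.1, two-sided, the smallest that 3 against 3 allows).

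The auxin-response, cell expansion and jasmonate lists had the lowest median Col-0 slopes of the 17 lists (-1.82, -0.92 and -0.76 per hour). Of 21 auxin-response genes 2 were positive and 18 negative (median -1.82 per hour, camera adjusted p = 3.4e-07, and adjusted p = 0.19 with an estimated correlation). Members were IAA29 (-3.22 ± 0.31), IAA2 (-1.38 ± 0.15) and IAA4 (AT5G43700, -1.23 ± 0.11). With times from 15 min 1 was positive and 11 negative. Of 14 cell expansion genes 0 were positive and 13 negative (camera adjusted p = 5.1e-06, and adjusted p = 0.059 with an estimated correlation). A member was EXPA1 (-1.49 ± 0.15). Of 25 jasmonate genes 2 were positive and 14 negative (2 and 15 adjusted over the list alone, camera adjusted p = 0.0019, and adjusted p = 0.54 with an estimated correlation). Examples were JAZ3 (-0.76 ± 0.07), JAZ7 (AT2G34600, -2.92 ± 0.40) and JAZ9 (-1.23 ± 0.13). Of 27 rapid stress regulators 3 were positive and 14 negative (camera adjusted p = 0.033, and adjusted p = 0.63 with an estimated correlation). They included CML24 (AT5G37770, -0.88 ± 0.09) and CBF2 (AT4G25470, -1.66 ± 0.19). Of 8 cell cycle genes 0 were positive and 6 negative (0 and 7 adjusted over the list alone, camera adjusted p = 0.00062, and adjusted p = 0.088 with an estimated correlation). A negative member was CYCB1;2 (AT5G06150, -0.92 ± 0.10). Of 17 clock genes 0 were positive and 9 negative (camera adjusted p = 0.038, and adjusted p = 0.17 with an estimated correlation). An example was PRR9 (AT2G46790, -0.83 ± 0.16). Of 14 root markers 1 was positive and 9 negative (camera adjusted p = 0.097). A member was SCR (AT3G54220, -0.52 ± 0.09). Without Col-0 series 1 or series 2 there were 5 or 3 negative, and with times from 15 min 2 positive and 2 negative. Of 20 mRNA decay factors 4 were positive and 7 negative (camera adjusted p = 0.43). CAF1A (AT3G44260, -0.86 ± 0.13) and DCP2 (-0.49 ± 0.07) were among the losses. Counts were 1 positive and 13 negative both with library size alone and with photosystem factors.

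Among the other lists the Col-0 slope counts depended on the scaling, in several also in direction. Of 17 heat shock genes 8 were positive and 0 negative (camera adjusted p = 0.0019, and adjusted p = 0.22 with an estimated correlation). A positive member was HSFA2 (AT2G26150, 1.54 ± 0.32). The heat shock counts were 4 and 1 with library size alone, with photosystem factors 4 and 0, and with times up to 60 min 3 and 0. Of 12 hypoxia genes 6 were positive and 1 negative (camera adjusted p = 0.016, and adjusted p = 0.16 with an estimated correlation), with PDC1 (0.84 ± 0.09), but 3 and 2 with library size alone and 3 and 1 with photosystem factors. Of 42 photosystem genes 17 were positive and 2 negative (camera adjusted p = 0.016, and adjusted p = 0.72 with an estimated correlation), but 9 were positive without Col-0 series 2, 1 was positive and 11 negative with library size alone, 2 and 11 with factors from the list itself, and 1 and 2 with times up to 60 min. Of 24 ribosomal protein genes 17 were positive and 0 negative (camera adjusted p = 0.0011, and adjusted p = 0.56 with an estimated correlation), but 0 and 4 with library size alone and 0 and 0 with photosystem factors. Of 28 genes of pattern-triggered defence 7 were positive and 3 negative (camera adjusted p = 0.037, and adjusted p = 0.63 with an estimated correlation), but 6 and 11 with library size alone. FRK1 (0.89 ± 0.10) and the chitin receptor CERK1 (AT3G21630, 0.58 ± 0.06) were positive. Of 22 abscisic acid genes 6 were positive and 2 negative (5 and 2 adjusted over the list alone, camera adjusted p = 0.16), but 2 and 4 with library size alone, 2 and 2 with photosystem factors and 1 and 2 with times up to 60 min. Of 24 salicylic acid genes 3 were positive and 4 negative (3 and 3 adjusted over the list alone, camera adjusted p = 0.97), but 1 and 2 without Col-0 series 1, 1 and 4 without series 2 and 3 and 2 without series 3. The salicylic acid counts were 1 and 9 with library size alone, with photosystem factors 1 and 7, and with times up to 60 min 0 and 2. Of 12 ethylene genes 3 were positive and 3 negative (4 and 3 adjusted over the list alone, camera adjusted p = 0.97), and 5 and 3 without Col-0 series 2, 1 and 6 with library size alone, 1 and 5 with photosystem factors and 0 and 4 with times up to 60 min. None of the 11 seed markers passed with TMM in edgeR, and 1 was positive with DESeq2 size factors, with the DESeq2 Wald test, with organelle genes removed or without Col-0 series 2.

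The slope difference between genotypes tested whether transcripts moved differently over time, relative to the bulk, in the mutant line. Of 25 jasmonate genes 13, and of 21 auxin-response genes 6, were lost more slowly relative to the bulk in the libraries labelled rh6812. Neither list passed camera with an estimated correlation (adjusted p = 0.47 and adjusted p = 0.52 with an estimated correlation). Both passed fry (fry adjusted p = 0.004 and adjusted p = 0.02). The histone H2B gene HTB2 (AT5G22880, -1.45 ± 0.07 in Col-0 and -0.05 ± 0.06 in rh6812, adjusted p = 1.4e-12) had one of the largest positive differences, with AT3G15450 (1.35 ± 0.19, -1.49 ± 0.15 in Col-0 and -0.14 ± 0.14 in rh6812, adjusted p = 2.5e-05), JAZ2 (AT1G74950, 1.25 ± 0.23, -1.40 ± 0.18 in Col-0 and -0.15 ± 0.16 in rh6812) and JAZ9 (-1.23 ± 0.13 in Col-0 and -0.03 ± 0.12 in rh6812). The receptor kinase genes LECRKA4.2 (AT5G01550, -1.45 ± 0.18, 1.66 ± 0.13 in Col-0 and 0.21 ± 0.11 in rh6812, adjusted p = 2.1e-06) and FRK1 (-0.73 ± 0.14, 0.89 ± 0.10 in Col-0 and 0.16 ± 0.09 in rh6812) and IGMT2 (AT1G21120, -0.73 ± 0.11), of indole glucosinolate synthesis, had some of the largest negative ones. Of 21486 genes 2977 passed, 1997 positive and 980 negative. In 1981 of the positive genes the Col-0 slope was below 0, and in 801 of these the rh6812 slope was at or above 0. Among the negative genes both slopes were above 0 in 560 and only the Col-0 slope was in 377. JAZ2, JAZ9 and FRK1 were no longer past the threshold with times up to 60 min only.

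The count of slope differences depended on single series and times. Without Col-0 series 1 there were 1732 genes, without rh6812 series 1 1836, with times up to 60 min 430, and in an F test with time as a factor 1123. The share of positive differences was 67.1% with TMM and 57.7% with DESeq2 size factors. It was 92.4% with library size alone (3065 positive and 253 negative) and 91.7% with factors from the photosystem list (1845 and 167). HTB2 and JAZ3 stayed past the threshold in each of these settings that gives a slope difference.

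**Figure D3:**
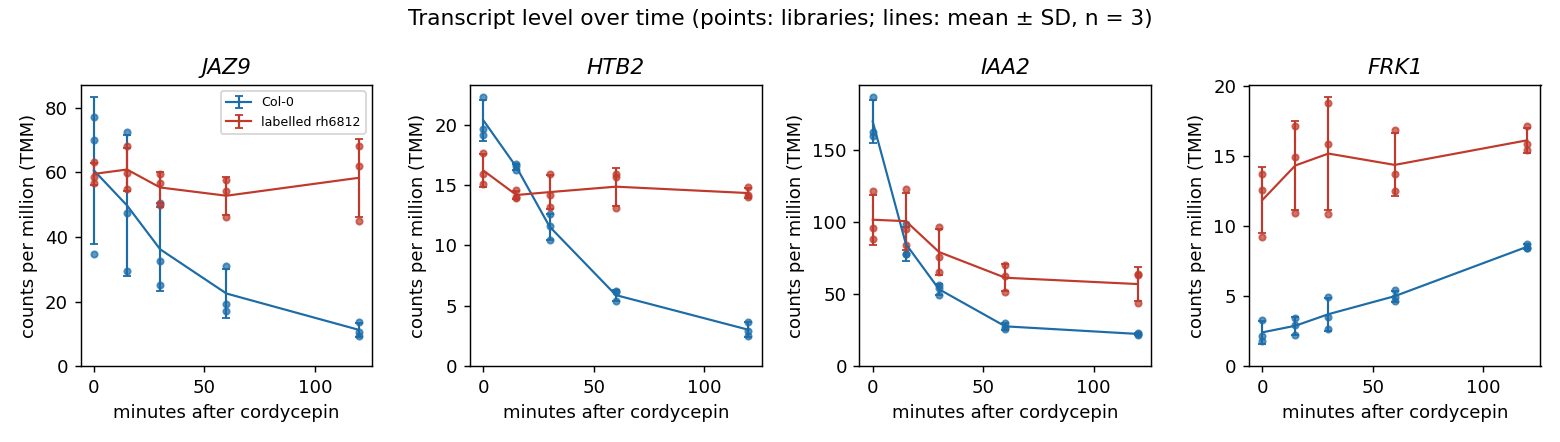
Abundance in CPM (vertical axes, TMM-scaled) of JAZ9, HTB2, IAA2 and FRK1 against minutes after cordycepin, with points for libraries and lines for means ± SD of 3. HTB2 went from 20.4 to 3.02 CPM in Col-0 and from 16.2 to 14.3 CPM in the libraries labelled rh6812 over 120 min, and JAZ9 from 60.7 to 11.3 and from 59.6 to 58.4 CPM.

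Of 25 jasmonate genes 13 were positive and 0 negative (15 and 0 adjusted over the list alone, median 0.74 per hour, camera adjusted p = 7.3e-07, and adjusted p = 0.47 with an estimated correlation). Examples were JAZ3 (0.74 ± 0.10, adjusted p = 4.9e-06) and JAZ6 (AT1G72450, 1.16 ± 0.23). Without Col-0 series 1, rh6812 series 2 or rh6812 series 3 the count was 8, with times up to 60 min 6 and with times from 15 min 5. Of 21 auxin-response genes 6 were positive and 0 negative (11 and 0 adjusted over the list alone, camera adjusted p = 0.00018, and adjusted p = 0.52 with an estimated correlation). They included IAA1 (AT4G14560, 1.51 ± 0.27, adjusted p = 0.00037) and IAA2 (0.93 ± 0.19). The count was 11 with library size alone and 2 with times from 15 min, where the list's median fell from 1.31 to 0.33 per hour. Of 14 cell expansion genes 5 were positive and 0 negative (8 and 0 adjusted over the list alone, camera adjusted p = 0.002, and adjusted p = 0.39 with an estimated correlation). Members were the brassinosteroid factor BZR1 (AT1G75080, 0.48 ± 0.07, adjusted p = 3.3e-05) and EXPA1 (0.88 ± 0.20). When rh6812 series 1 was left out 3 were positive, with times up to 60 min 1 and with times from 15 min 3. BZR1 was not past the threshold with times up to 60 min only. Of 27 rapid stress regulators 6 were positive and 0 negative (camera adjusted p = 0.094). An example was the calmodulin-like CML24 (0.86 ± 0.12, adjusted p = 9.1e-06). When Col-0 series 3, rh6812 series 1 or rh6812 series 2 was left out 3 were positive. With times up to 60 min 3 were positive, and with times from 15 min 2 were positive and 1 negative. Camera called the heat shock list (of 17 genes 0 were positive and 1 negative, median -0.20, camera adjusted p = 0.022, and adjusted p = 0.53 with an estimated correlation) and the ribosomal protein list (of 24 genes 0 were positive and 1 negative, median -0.08, camera adjusted p = 0.0069, and adjusted p = 0.71 with an estimated correlation) downwards with 1 call each. With DESeq2 size factors 2 and 4 of their genes were negative, with library size alone 1 and 0 (medians -0.12 and 0) and with photosystem factors 0 and 0 (medians -0.15 and -0.02). Leaving out Col-0 series 3, rh6812 series 1 or rh6812 series 2 gave 0 negative heat shock genes, and leaving out rh6812 series 3 gave 3. Positive and negative calls numbered 3 and 2 of 20 for mRNA decay (4 and 2 adjusted over the list alone), 3 and 1 of 24 for salicylic acid immunity with PAD4 (0.55 ± 0.12), 2 and 2 of 28 for pattern-triggered defence with MPK3 (AT3G45640, 0.62 ± 0.15) (2 and 3 adjusted over the list alone), 4 and 0 of 17 for the clock, 2 and 0 of 8 for the cell cycle with CYCB1;2 (0.60 ± 0.13) and 2 and 0 of 14 for root markers with SCR (0.53 ± 0.12) (2 and 1 adjusted over the list alone). The ethylene, abscisic acid, hypoxia and photosystem lists had at most 1 call in either direction and the 11 seed markers none, and most of these small counts moved by more than 1.5 times when 1 series was left out. Counts for mRNA decay with library size alone were 5 positive and 0 negative, those for pattern-triggered defence 5 and 2, and the clock had 2 positive with DESeq2 size factors, 0 with times up to 60 min and 1 with times from 15 min.

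Classes of genes by Col-0 slope showed where the differences lay. Genes were placed in equal-sized classes by the slope of Col-0 series 1, and the slope difference was taken from the other 2 series of each genotype. In the class lost fastest (4298 genes) the median slope was -0.504 in Col-0 and -0.211 in the libraries labelled rh6812, a median difference of 0.306, and 83.9% of its genes had a positive difference. In the class with the highest Col-0 slopes (4297 genes) the medians were 0.306 and 0.139, a difference of -0.175, with 14.5% positive. With classes from series 2 and 3 the fastest-lost class gave 0.263 and 0.274 and the class with the highest slopes -0.157 and -0.216. The interquartile range of slopes was 0.445 ± 0.022 per hour over the 3 Col-0 series and 0.309 ± 0.035 over the 3 series labelled rh6812 (SD, n = 3, exact permutation p = 0.1, two-sided, the smallest that 3 against 3 allows).

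**Figure D4:**
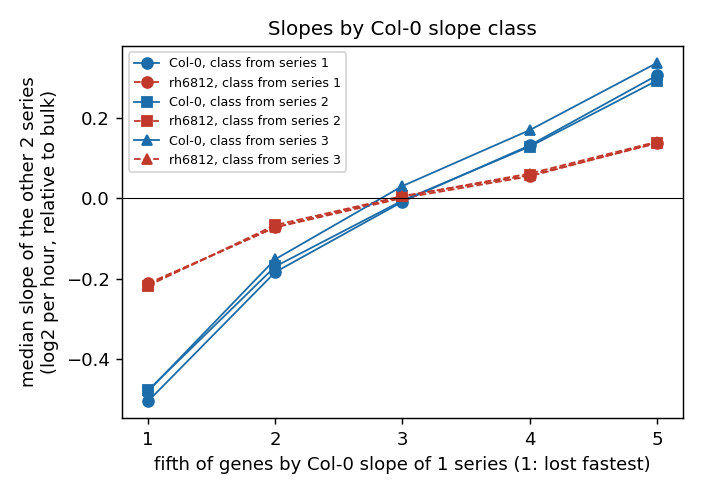
Median slope (vertical axis, log2 per hour relative to the bulk) of genes classed in equal steps by the slope of 1 Col-0 series (horizontal axis, 1 lost fastest), each median taken from the other 2 series of each genotype. Lines for the libraries labelled rh6812 are flatter, from -0.211 to 0.139 against -0.504 to 0.306 in Col-0 with classes from series 1; with library size alone or photosystem factors most slopes of both genotypes are negative.

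Slope differences were set against the change in total poly(A)+ RNA to ask whether transcripts held longer were also more abundant. They tended to be less abundant in the libraries labelled rh6812. This direction rests on the poly(A)+ set, in which time-of-day regulated transcripts could carry a shift between the genotypes. Among 1988 genes with a positive slope difference the median total RNA change was -0.15, with 554 higher and 830 lower, and among 938 genes with a negative one it was 0.17, with 410 higher and 253 lower. Among genes with no call it was -0.02. JAZ9 and JAZ2 belonged to the smaller class that was both held longer and more abundant in total poly(A)+ RNA, but at 0 min of the series themselves neither was called higher (JAZ9 60.7 CPM in Col-0 and 59.6 CPM in rh6812, JAZ2 53.1 and 33.4 CPM). IAA1 and IAA2 were held longer and less abundant in total RNA. Across 20319 genes r was -0.148 and rho -0.098, and rho was -0.032, -0.073 and -0.149 with slopes of replicate 1, 2 or 3 alone. Of 2047 genes called in both tests 807 (39.4%) had the same sign, against 641 and 307 expected in the 2 same-sign classes for independent lists (554 and 253 seen, Fisher's exact odds ratio 0.412, p = 2.7e-20 across genes, which are not independent replicates).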

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

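Of the tests in this part, those of exchanged labels and of shared reads for RH6, of the 0 min libraries for the slopes, and all tests of the clock genes were chosen after the result was seen. The comparison of slope classes from separate libraries was planned, but its use as a test was set after its value was seen. The tests of equal nuclear counts and of one factor for all transcripts, and all the splits of the samples, were chosen before.

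Results stand here because an effect differed between groups by a test of the difference itself. The genotype change differed between polysome and total RNA for 2044 genes, the slope after cordycepin differed between genotypes for 2977 genes, and for RH6 the log2 genotype change in polysome RNA minus that in total RNA was -0.76.

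RH6 was more abundant in the libraries labelled rh6812, by 1.27 in total RNA and by 3.42 at 0 min. An exchange of the genotype labels is argued against, since RH8 lay below every Col-0 library of the same RNA and time in 21 of 21 libraries labelled rh6812. Reads of RH8 and RH12 counted as RH6 are argued against as the whole cause, since RH6 gained 342 CPM at 0 min and the other 2 lost 39.3 CPM together, a ratio of 8.71. What stays open, untested, is what the RH6 reads are: an insertion allele may give a truncated or chimeric transcript, and the smaller gain in poly(A)+ than in rRNA-depleted RNA may come from a transcript with little poly(A), but gene counts hold no position along the transcript. A response of RH6 to the loss of RH8 and RH12 is also open, as is any other effect of genotype.

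Slopes after cordycepin were narrower in the libraries labelled rh6812, and the fastest-lost genes of Col-0 moved towards the bulk. Classing and comparing genes in the same libraries is argued against as the cause, since classes from 1 series and differences from the others gave a median of 0.306 in the fastest-lost class. The rh6812 to Col-0 ratio of the interquartile range was 0.694 with all libraries, 0.703 with every library thinned to 5656282 nuclear counts and 0.716 without 0 min, which argues against unequal nuclear depth and against the 0 min libraries alone. In a test of a single factor for all transcripts, 876 genes departed from a common factor of 0.462, of which 554 are among the 2977. The factor had an SD of 0.021 over 3 estimates that share libraries, and the test took it as exact. For genes of mean log2 CPM of at least 3, classed by series 1, the factor was 0.349, so that of all genes does not hold for them. A weaker or later block of RNA synthesis need not change straight-line slopes by one factor. The test therefore cannot decide on such a block. A hypothesis that remains is slower decay of short-lived transcripts in the mutant line. A block of synthesis that is weaker or later there, or acts unequally on different genes, remains beside it, since no library measures synthesis.

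Clock transcripts differed between the genotypes of the poly(A)+ libraries. Of 12 clock genes 11 changed in total RNA as one shift of phase would give, with LHY 3.63 higher and PRR5 3.19 lower. A genotype change present at every harvest is argued against for LHY and CCA1, which were lower at 0 min (-0.97 and -0.45), but it stays open for the 8 later genes, of which 3 (PRR9, PRR7 and PRR5) were lower in both sets and none was called in opposite directions. A difference in harvest time between the genotypes of the poly(A)+ set and a genotype effect on phase cannot be told apart, since no harvest times are given and each genotype has its own libraries. Every time-of-day regulated transcript of the total and polysome comparisons could carry the same shift.

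Other splits of the same libraries were fitted for each count. With 3 against 3 the 10 splits are too few for a share under 0.05: the real split was the 1 with most calls in total RNA (13536, highest other 0), in polysome RNA (13298, highest other 0), between polysome and total RNA in Col-0 (12083, highest other 0) and in the libraries labelled rh6812 (11140, highest other 0), at 0 min (10390, highest other 21) and for the slope difference (2977, highest other 0). For the slope in Col-0 (10894, highest other 2254) and in the libraries labelled rh6812 (4662, highest other 2) the real order of times had the most calls of 40 orders. That share is under 0.05, but the other orders mixed times between the series of a genotype. For these slopes within a genotype chance is therefore argued against and not excluded. The other 3 against 3 splits mixed the compared groups, which puts the difference between them into the spread within groups. Their low counts therefore add nothing, and these splits cannot decide on chance. For ribosome association 8 of 100 drawn splits, the real one included, called at least the real 2044 genes (highest other 15363). The 7 others left at least 1 RNA population unmixed by genotype, so they carry its genotype effect, and the highest is the exchange of genotypes in polysome RNA alone, which adds the genotype effects of both populations. The 75 splits that mixed both populations called at most 0. This count of splits therefore decides nothing about chance for ribosome association.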

How the results depend on the processing

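One alternative in this part, the relation of slopes to total RNA with slopes from 15 to 120 min, was chosen after the data were seen. For the 11 counts and summary values that answer a comparison, all but 11 of 134 alternative values stayed within their bound. The bound was 1.5 times for counts of genes and the SD over replicates for summary values. For counts it took the total alone, not the direction or which genes were called. With library size alone Col-0 slopes stayed within it at 1373 positive and 9977 negative, against 5030 and 5864. There 7239 of the 10894 genes were shared. For named genes 7100 of 7553 values kept their direction and side of the threshold, 321 lost the call, 120 gained one and 12 reversed. For list counts 1282 of 1513 stayed within 1.5 times, 203 moved and 28 reversed. The cause of these changes was not tested, except that a fit with fewer libraries or times has less power. Organelle removal gives no other value for poly(A)+ results, which hold no organelle counts. Depth limits rare transcripts most in rh6812 polysome RNA, where 3 counts over the group are 0.0933 CPM, against 0.0533 CPM in Col-0 polysome RNA.

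Slopes from 0 to 60 min called 6483 genes in Col-0, 1128 in the libraries labelled rh6812 and 430 for the difference, and slopes from 15 to 120 min called 2684 in the libraries labelled rh6812. Time as a factor, an F test of any genotype by time term, called 1123. Classes from replicate 2 and replicate 3 gave 0.263 and 0.274 in the fastest class. Leaving out 1 series gave 1732 to 2796 genes for the slope difference and 2598 to 3236 for slopes in the libraries labelled rh6812. Slopes against total RNA gave a rho of -0.107 for genes of mean log2 CPM of at least 3, -0.104 with slopes from 0 to 60 min and -0.069 with slopes from 15 to 120 min, against -0.098. The DESeq2 Wald test called 12738 genes in total RNA, 12694 in polysome RNA, 1790 for association, 10091 at 0 min, and 11139, 4999 and 3448 for the slopes in Col-0, in the libraries labelled rh6812 and their difference.

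The labels give groups the same replicate numbers without saying that they mark a shared sample. With the number as a replicate block 13879 genes were called in total RNA, 13613 in polysome RNA, 2691 for association, 12602 and 11637 between polysome and total RNA, 11224 at 0 min, and 11446, 5445 and 3742 for the slopes, none moved by more than 1.5 times. With blocks within genotype the slope counts were 11792, 5952 and 4265. Same-numbered libraries correlated at -0.01 to 0.18 (median 0.02) in the poly(A)+ set and -0.17 to 0.43 (median 0.13) in the rRNA-depleted set. The medians of differently numbered libraries were -0.01 and -0.07, so these are not correlations of whole expression profiles. In the 2 sets 12 of 12 and 30 of 30 libraries correlated best with their own number, a hint from the data and not from the design.

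List counts turned as follows. With library size alone the larger direction reversed for ribosomal proteins at 0 min (1 lower), pattern-triggered defence in association (0 lower) and in Col-0 slopes (6 positive), and Col-0 slopes of abscisic acid (2 positive), photosystem (1 positive) and ribosomal protein genes (0 positive). With photosystem factors 2 photosystem genes had a positive Col-0 slope, and from 0 to 60 min 1 photosystem and 1 abscisic acid gene. With the replicate block pattern-triggered defence had 1 lower in association. From 15 to 120 min 0 abscisic acid genes had a negative slope difference, and photosystem genes with a positive one numbered 1 with the DESeq2 Wald test and 2 with the replicate block within genotype.

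Leaving out 1 library gave 1 to 3 higher root markers in polysome RNA, 0 to 1 lower pattern-triggered and 0 to 2 higher heat shock genes in association, and 2 to 5 higher mRNA decay factors at 0 min. Leaving out 1 time series gave 2 to 4 negative Col-0 slopes of salicylic acid genes and 0 to 1 positive slope differences of photosystem genes. With 1 library left out PER1 ran from -2.30 to 0.54 in polysome RNA and from -1.21 to 1.63 in association, and AT4G28520 in association from -1.38 to 3.74. Col-0 slopes with library size alone were -0.10 for RH8, -0.14 for RH12, -0.01 for RPS13A and -0.01 for RPL3A, and with photosystem factors -0.08 for RH8 and -0.11 for RH12. From 0 to 60 min the Col-0 slope of PER1 was -0.34 and the slope difference of LDH1 -0.07, and from 15 to 120 min the slope difference of SRO5 was -0.02.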

Other observations

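In this part the choice of the histone genes and their test were made after values were seen, and both tests of the jasmonate list were chosen before.

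Core histone genes are outside the lists and were chosen, by their names in the names table, after HTB2 stood out. A histone gene without such a name would be missing, and HIS4 is the only H4 gene in the set. Of 29 tested, 20 had a positive slope difference and 0 a negative one with edgeR, and 20 were positive without 0 min too. HTB2 was lost at -1.45 ± 0.07 per hour in Col-0 and -0.05 ± 0.06 in the libraries labelled rh6812, the H3.1 gene AT5G65360 at -1.25 and -0.11 (difference 1.14 ± 0.07), and HTB9 at -0.98 and -0.02. All 5 replication-type H3.1 genes were positive, against 1 of 3 H3.3 genes. The H2A.Z genes HTA8, HTA9 and HTA11 had differences of -0.04, 0.04 and 0.06. In total RNA 13 of 28 were higher and 6 lower. Near-identical histone copies share reads, so values of single copies are uncertain.

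A hypothesis is that core histone transcripts depend on the helicases for decay more than other short-lived transcripts do. The median difference of all 29, H3.3 and H2A.Z genes included, was 0.64, against 0.32 (0.17 to 0.48) in 10000 lists matched on Col-0 slope, percentile 99.99, and 16 of the 29 departed from a common factor for all transcripts. These values cannot decide whether fast loss in Col-0 is the whole cause. The genes were picked from the same data, and the matched lists drew genes independently, while histone copies share reads. The lists were matched on Col-0 slope and not on abundance. The common factor was 0.462, but 0.349 for genes of mean log2 CPM of at least 3. Part of the 16 departures may therefore come from a factor set too high. Histone transcripts follow the S phase, and poly(A) tails and cell division were not measured after cordycepin, so the hypothesis may not hold in other samples.

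A hypothesis for the jasmonate list is that its transcripts are held longer as a group. The list's median difference of 0.74 lay at percentile 100 of 10000 lists matched on Col-0 slope (median 0.33, 0.15 to 0.51), which argues against fast loss in Col-0 alone. Genes were matched on Col-0 slope and not on abundance. Matched genes do not share the list's correlation of 0.343, and the list did not pass camera when it was allowed for (camera adjusted p = 0.47 with an estimated correlation). The list passed fry, which keeps the correlation but does not compare the list with other genes (fry adjusted p = 0.004). Without 0 min 5 members were past the threshold with a median of 0.57 over 24 genes, so a part played by the 0 min libraries alone cannot be told apart from slower loss. In Col-0 JAZ2 stood at 53.1 ± 31.3 CPM at 0 min, a wide spread, against 33.4 ± 1.53 CPM in the libraries labelled rh6812. A response to handling that differs between samples at 0 min could add to the slopes of these genes.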
